A study of Caenorhabditis elegans with 12 samples.

How the data were processed

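Whole L1 larvae of Caenorhabditis elegans N2 were sequenced as 12 mRNA libraries, 3 biological replicates in each of 4 groups that combine 100 or 500 mM NaCl with presence or absence of OP50 bacteria for 24 h at 25 °C. Libraries were made with a kit that does not keep strand, per the labels' protocols, so reads from overlapping or antisense genes cannot be told apart. The deposited per-sample files hold raw read counts per gene, made by the authors with Bowtie 1.1.2 and HTSeq, per the submitters' processing notes. Their HTSeq settings are not stated, and the genome build of the counts is not given in the sources used here. The authors' deposited workbook holds edgeR exact-test tables with log2 fold changes and log2 average CPM. Those tables also give p-values and false discovery rates, computed by the authors on genes with CPM over 1 in 3 libraries, per the workbook's notes sheet. The deposited tables served for a comparison of calls only, and the deposited CPM table was not used. The count table in the workbook was identical to the 12 per-sample files, and no pair of libraries held identical counts.

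The count files list 44968 features by sequence name and 5 summary lines, which were left out of the gene table and used for alignment, no-feature and ambiguous shares. Gene symbols and biotypes came from the RefSeq gene table of assembly WBcel235, which named 43592 of the features, and 20 features were ribosomal RNA genes. The deposited tables' gene identifiers matched 15881 features. Because the build of the counts is not given, no coordinates are printed. Of the symbols in the deposited tables, 10 had been turned into dates and were matched by identifier instead. All 12 libraries were mapped to their groups.

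Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups with its defaults (minimum count 10, minimum total count 15), which left 18028 genes, rRNA genes included, and libraries were scaled by TMM. All 12 libraries entered a single model with 1 coefficient per group, so that the groups share an estimate of the spread, and contrasts were tested two-sided with the robust quasi-likelihood F-test. Genes passed, or were called, at a Benjamini-Hochberg adjusted p under 0.05, adjusted per comparison. The SE of a log2 fold change was taken as its size divided by the square root of F. Of the comparisons, 4 set 1 factor against another at a fixed level of the second, another is the interaction, and the last sets fed high-salt against unfed low-salt larvae. CPM are counts per 1000000 of the TMM-scaled library size. Principal components were taken of log2 CPM. The steps were tested on simulated counts: for 500 against 100 mM NaCl with food the test recovered 4 of 100 genes changed by 2-fold and 61 of 100 changed by 4-fold among 18028, with 13 false calls, and counts simulated with no change for lack of food at 100 mM NaCl gave 1 false call.

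Before the data were examined, 36 gene lists were fixed: osmolyte and water transport, ion transport and volume, epidermal antimicrobial peptides, cytosolic chaperones, endoplasmic reticulum stress, genes raised by DAF-16, insulin-like peptides, insulin, TOR and AMPK pathway, lipases and fatty-acid oxidation, fatty-acid synthesis, glycolysis, gluconeogenesis, ribosomal proteins, nucleolus, mitochondrial respiration, proteasome, autophagy, cell cycle, cuticle collagens, annular furrow collagens, molting, digestive enzymes, C-type lectins, cytochrome P450, glucuronosyltransferases, glutathione S-transferases, vitamin B12 metabolism, dauer genes, heterochronic genes, vitellogenins, and markers of embryo, germline, neuron, muscle, intestine and epidermis. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 36 lists. Under the estimated correlation 2 of 102 list calls held. Lists overlap, so their results are not independent. Whole larvae hold all tissues, so marker lists describe the animal, and a gene on a marker list can be expressed in other tissues.

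Named genes were chosen by a rule fixed at the same time: 12 focal genes, the 6 highest and 6 lowest called log2 fold changes among genes with a mean of at least 10 CPM whose groups do not overlap, and up to 4 members of each list with the smallest p. The rule names 161 genes for lack of food at 100 mM NaCl, 161, 153 and 156 for the other contrasts of 1 factor, 160 for the interaction and 157 for the comparison of both arrests, and the text names part of them. The 12 focal genes are gpdh-1, gpdh-2, hmit-1.1, nlp-29, sod-3, daf-16, daf-28, icl-1, acdh-1, acs-2, col-19 and mlt-10.

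Depth ranged from 5613260 to 76542711 reads on genes. Alternatives fixed before the data were examined were the replicate letter as a block, DESeq2 1.42.0, edgeR's exact test, RLE and upper-quartile factors, no count filter, a filter of 5 CPM in 3 libraries, fits of only the 2 groups compared, a fit without robust estimation, and fits without each library in turn. Alternatives chosen after seeing the data were leaving out rRNA genes before scaling, leaving out unfed high-salt A and fed high-salt C, the share of reads outside genes as a covariate, voom with library weights, and upper-quartile factors for lists and named genes. Splits of the samples into other groups of the same sizes were counted for each comparison, all 10 for 2 groups of 3 and 100 drawn with a fixed seed for the interaction, for which all 20 splits that keep the low-salt groups whole were also counted. A correlation between libraries used 100000 permutations.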

Results

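Whole first-stage (L1) larvae of the Caenorhabditis elegans wild-type strain N2 were profiled by mRNA sequencing after 24 h at 25 °C on plates with 100 or 500 mM NaCl, with or without the bacterium OP50 as food. The 12 libraries fall into 4 groups of 3 biological replicates, lettered A to C, named here fed low-salt, unfed low-salt, fed high-salt and unfed high-salt. The series title names osmotic and starvation arrest of L1 larvae. The comparisons ask which transcripts differ between arrested and fed low-salt larvae, how far both arrests share genes, and whether salt and food interact. All libraries are from 24 h, so growth of fed low-salt larvae is not separated from either treatment. Reads on genes numbered 16352879, 16622162 and 76542711 in fed low-salt A, B and C, and 16109742, 18759684 and 18219252 in unfed low-salt A, B and C. They numbered 14355870, 20659851 and 17380979 in fed high-salt A, B and C, and 5613260, 17121600 and 15429996 in unfed high-salt A, B and C. Expression is given as counts per 1000000 reads (CPM, mean ± SD, n = 3 libraries), changes as log2 fold changes ± standard error (SE), and adjusted p-values are those of edgeR's quasi-likelihood test over all 18028 genes tested, with Benjamini-Hochberg adjustment. Fold changes are unshrunken.

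Reads on ribosomal RNA (rRNA) genes made up 4.68%, 2.65% and 2.98% of the reads on genes in fed low-salt A, B and C, and 6.61%, 1.32% and 12.4% in the unfed low-salt libraries. The share was 9.13%, 39.9% and 81.8% in fed high-salt A, B and C, and 14.9%, 6.32% and 18.2% in the unfed high-salt libraries. Non-rRNA reads ranged from 3167905 in fed high-salt C to 74258237 in fed low-salt C. In unfed high-salt A 38.6% of reads aligned and 17.1% of aligned reads lay outside annotated genes, against 70.1% to 91.3% aligned and 1.87% to 5.90% outside genes in the other 11 libraries. The 95% Wilson intervals of the shares of rRNA and of reads outside genes were at most 0.0588 percentage points wide. Those intervals cover counting error only, since PCR copies are not independent molecules. The first principal component of log CPM held 47.3% of the variance and separated all 6 low-salt libraries, at scores of -124 to -18.8, from all 6 high-salt libraries, at 62.3 or more. The second held 20.3%, and unfed high-salt A had its highest score, 145. Unfed low-salt C lay at a first-component score of -99.4, beside the fed low-salt libraries at -124 to -114, while unfed low-salt A and B lay at -18.8 and -51.9. Correlations of log CPM across genes within a group were 0.984 to 0.986 in fed low-salt, 0.944 to 0.945 in unfed low-salt, 0.925 to 0.950 in fed high-salt and 0.810 to 0.958 in unfed high-salt larvae.

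**Figure D1:**
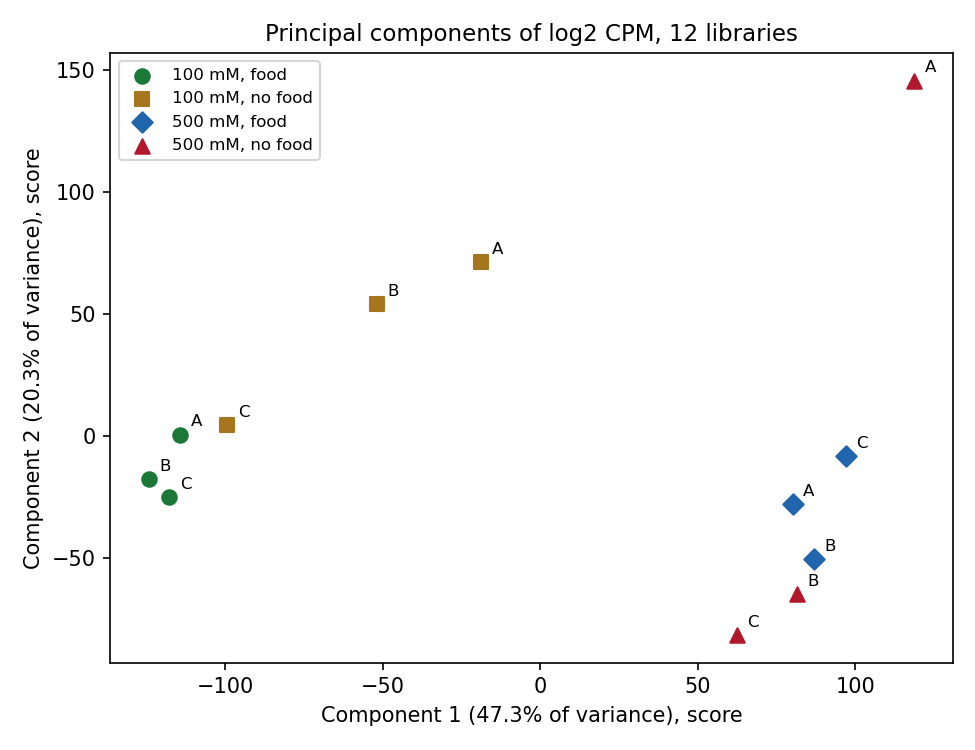
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, 1 point per library, coloured by group and lettered by replicate. The low-salt libraries lie at first-component scores below 0 and the high-salt libraries above 0, unfed low-salt C lies beside the fed low-salt libraries, and unfed high-salt A lies apart at 145 on the second component.

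Lack of food at 100 mM NaCl was examined first, by comparing unfed with fed low-salt larvae. Transcripts of heat shock chaperones fell together. The transcript of hsp-70 (C12C8.1), a heat-inducible chaperone, fell from 62.5 ± 15.0 to 2.84 ± 1.99 CPM, a log2 fold change of -4.45 ± 0.55 with an adjusted p of 0.00113. Some germline, elongase, sugar and methionine metabolism genes fell as well, while 7 insulin-like peptide genes and the desaturase gene fat-5 (W06D12.3) rose. The lowest log2 fold change among the genes named by the fixed rule was that of lep-5 (H36L18.2), a long non-coding RNA of larval timing. It fell by 6.39 ± 0.69 on the log2 scale, with fed libraries that ranged widely, at 155 ± 115 CPM, against 1.84 ± 0.298 CPM without food.

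Of 25 cytosolic chaperone genes tested, 15 fell and none rose without food, and adjusted over the list alone 17 fell and 1 rose. The camera test, which sets a list against all other genes with a preset correlation, gave an adjusted p of 5.79e-16. The list's adjusted p = 0.181 with an estimated correlation. F44E5.4 and F44E5.5, near-identical hsp-70 copies whose reads cannot be told apart with certainty, fell from 1031 ± 243 to 59.1 ± 29.4 CPM and from 1056 ± 259 to 60.6 ± 30.9 CPM. The transcript of hsp-110 (C30C11.4) fell by 2.29 ± 0.37 on the log2 scale. Of 18 genes of the endoplasmic reticulum stress response, 4 fell, and 10 fell adjusted over the list alone (camera adjusted p = 1.54e-07; adjusted p = 0.369 with an estimated correlation). Among them hsp-4 (F43E2.8), the BiP chaperone, fell from 229 ± 53.5 to 59.4 ± 10.4 CPM.

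Germline markers also fell: 15 of 28 fell and none rose, and 18 fell adjusted over the list alone. The camera adjusted p was 1.61e-15, and the adjusted p = 0.0838 with an estimated correlation. The genes pgl-1 (ZK381.4) and pgl-3 (C18G1.4), which encode proteins of germ granules, had log2 fold changes of -2.09 ± 0.37 and -2.07 ± 0.38. The germ granule gene glh-1 (T21G5.3) fell from 167 ± 24.4 to 36.3 ± 15.3 CPM, and the Argonaute gene csr-1 (F20D12.1) fell by 1.89 ± 0.32. Of 26 embryo markers 2 fell, both also adjusted over the list alone, among them cey-2 (F46F11.2), which fell from 31.7 ± 4.32 to 7.90 ± 1.76 CPM. Their camera adjusted p was 0.280.

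Metabolic genes fell in several lists. Of 22 fatty-acid synthesis genes 6 fell and 1 rose, and 8 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00751; adjusted p = 0.419 with an estimated correlation). The elongase genes elo-5 (F41H10.7), elo-2 (F11E6.5) and elo-6 (F41H10.8) fell, at log2 fold changes of -3.04 ± 0.41, -2.47 ± 0.35 and -1.58 ± 0.27. The member that rose, fat-5, went from 19.3 ± 2.53 to 122 ± 26.1 CPM. Outside the desaturases and elongases, hacd-1 (R09B5.6) fell from 67.5 ± 2.48 to 3.95 ± 1.19 CPM. Of 38 lipase and fatty-acid oxidation genes 9 fell and 3 rose, and 13 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.226 with an estimated correlation). In this list acox-2 (F08A8.2), a neighbour and paralog of acox-1 whose reads are uncertain for that reason, fell by 3.87 ± 0.47 on the log2 scale and acs-2 (F28F8.2) fell by 2.94 ± 0.71. The lysosomal lipase gene lipl-3 (R11G11.14) rose by 4.10 ± 1.04. Of 19 genes of vitamin B12, propionate and methionine metabolism 8 fell and none rose, and 15 fell adjusted over the list alone (camera adjusted p = 2.49e-10; adjusted p = 0.181 with an estimated correlation). Among them ahcy-1 (K02F2.2) fell by 2.28 ± 0.43, mel-32 (C05D11.11) fell by 1.92 ± 0.38 and acdh-1 (C55B7.4) fell by 1.51 ± 0.44 on the log2 scale. Of 12 glyoxylate, gluconeogenesis and glycogen genes 4 fell, and 9 fell adjusted over the list alone (camera adjusted p = 1.96e-08; adjusted p = 0.181 with an estimated correlation). Among them were pck-1 (W05G11.6) at -2.08 ± 0.33 and fbp-1 (K07A3.1) at -1.75 ± 0.29. Of 18 glycolysis genes 6 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.79e-07; adjusted p = 0.369 with an estimated correlation). Members of this list include ldh-1 (F13D12.2) at -1.26 ± 0.27 and enol-1 (T21B10.2) down from 911 ± 116 to 370 ± 95.1 CPM. Of 45 mitochondrial respiration genes 5 fell, among them asb-1 (F35G12.10) at -1.33 ± 0.26, and 5 fell adjusted over the list alone (camera adjusted p = 3.41e-09; adjusted p = 0.419 with an estimated correlation). No proteasome gene of 33 and no autophagy or lysosome gene of 50 passed the test, over all genes or over the list alone, although camera placed both lists below the other genes, at adjusted p = 6.65e-10 and 0.00321. With an estimated correlation those were adjusted p = 0.419 and adjusted p = 0.748.

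Insulin-like peptide genes went the other way: 7 of 30 rose and none fell, and 9 rose adjusted over the list alone, with a median log2 fold change of 1.23. The camera adjusted p was 0.000242, and the adjusted p = 0.419 with an estimated correlation. The genes ins-17 (F56F3.6) and ins-20 (ZK84.7) rose by 1.68 ± 0.33 and 3.31 ± 0.67 on the log2 scale, and ins-1 (F13B12.5) from 15.7 ± 2.13 to 41.6 ± 12.7 CPM, while daf-28 (Y116F11B.1), another member, had a log2 fold change of 0.35 ± 0.32 and an adjusted p of 0.491. Of 31 neuron markers 5 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00343; adjusted p = 0.661 with an estimated correlation). Examples are the neuropeptide genes flp-1 (F23B2.5) and flp-9 (C36H8.3) at 1.55 ± 0.34 and 1.51 ± 0.33. The TGF-beta ligand gene daf-7 (B0412.2) rose from 70.7 ± 20.2 to 145 ± 6.58 CPM, and daf-9 (T13C5.1), a gene of steroid hormone synthesis, fell by 2.09 ± 0.33 on the log2 scale. In their list of 15 dauer genes 1 rose and 2 fell, and 1 rose and 3 fell adjusted over the list alone. Of 13 heterochronic genes, which time larval development, lin-28 (F02E9.2) rose by 1.33 ± 0.31 and lin-46 (R186.4) fell by 1.48 ± 0.32 on the log2 scale, and the same 1 rose and 1 fell adjusted over the list alone. Of 42 digestive enzyme genes 3 rose and 3 fell, and 6 rose and 5 fell adjusted over the list alone, with the lysozyme genes ilys-3 (C45G7.3) and ilys-2 (C45G7.2) up from 0.680 ± 0.425 to 33.8 ± 22.1 CPM and from 2.06 ± 0.890 to 41.3 ± 30.2 CPM.

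Lists of cuticle building, growth and osmotic defence were examined in the same comparison. Of 166 cuticle collagen genes 21 fell and 1 rose, and 26 fell and 6 rose adjusted over the list alone, with col-145 (B0222.7) at -2.92 ± 0.49. Their median of -0.06 became 0.11 with upper-quartile scaling, the camera adjusted p was 0.0143, and the adjusted p = 0.779 with an estimated correlation. None of 82 ribosomal protein genes passed the test (median log2 fold change -0.03, and 0.18 with upper-quartile scaling), and of 46 cell cycle and DNA replication genes 1 rose, 0 adjusted over the list alone. Of 17 osmolyte and water transport genes 4 fell, and 6 fell and 1 rose adjusted over the list alone. The camera adjusted p was 0.0225, 0.0667 without unfed low-salt A and 0.419 with an estimated correlation. With upper-quartile factors 1 rose and 0 fell. The glycerol synthesis genes gpdh-1 (F47G4.3) and gpdh-2 (K11H3.1) stood at -0.56 ± 0.34 and -0.66 ± 0.25, at adjusted p = 0.299 and 0.113. The focal genes daf-16 (R13H8.1), sod-3 (C08A9.1), icl-1 (C05E4.9), nlp-29 (B0213.4), hmit-1.1 (Y51A2D.4) and mlt-10 (C09E8.3) did not pass the test either, with adjusted p-values of 0.885, 0.244, 0.263, 0.861, 0.895 and 0.842.

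In all, 1384 of 18028 genes passed the test at an adjusted p under 0.05, with 643 higher and 741 lower without food, and 1224 of them differed by more than 2-fold. The median log2 fold change of all genes was 0.15, and 0.36 with upper-quartile scaling, under which 1099 rose and 548 fell. In 41.4% of genes the 3 fed and 3 unfed libraries did not overlap in CPM, where chance gives 10%. The count rests on single libraries: it was 376, 218 and 306 without fed low-salt A, B and C, 333 and 220 without unfed low-salt A and B, 2179 without unfed low-salt C, 889 without fed high-salt B and 2989 without unfed high-salt A. Without unfed high-salt A (lowest alignment) and fed high-salt C (highest rRNA share) 3238 genes passed. Of the 47 called genes followed in the fits with 1 library left out, 26 stayed called in each of the 12 fits, among them hsp-70, F44E5.4, F44E5.5, hsp-110, hsp-4, glh-1, pgl-1, pgl-3, csr-1, elo-2, elo-5, elo-6, fat-5, hacd-1, acox-2, pck-1, fbp-1, ahcy-1, daf-9, cey-2, col-145 and lep-5. Without fed low-salt A, B or C the calls of 10, 19 and 15 of the 47 were lost, and without unfed low-salt A, B or C those of 14, 19 and 1. The calls of acs-2, acdh-1, lipl-3, mel-32, enol-1, ldh-1, asb-1, ins-1, ins-17, ins-20, flp-1, flp-9, daf-7, lin-28, lin-46, ilys-2 and ilys-3 were among those lost.

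High salt in the presence of food was examined by comparing fed high-salt with fed low-salt larvae. Cuticle collagen and molting genes, genes of ribosomes, respiration and proteolysis, and genes of digestion and fat oxidation fell, while single stress and osmolyte genes such as sod-5 and gpdh-1 rose. The collagen gene col-17 (F11G11.10) fell from 1241 ± 360 to 0.881 ± 0.832 CPM, and rol-6 (T01B7.7) from 418 ± 129 to 1.61 ± 1.07 CPM, a log2 fold change of -8.23 ± 0.54 at an adjusted p of 6.47e-07. The superoxide dismutase gene sod-5 (ZK430.3) rose from 1.74 ± 1.09 to 582 ± 323 CPM, and gpdh-1, which encodes an enzyme of glycerol synthesis, rose from 15.2 ± 5.40 to 43.1 ± 20.3 CPM, a log2 fold change of 1.52 ± 0.34 at an adjusted p of 0.00278.

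Of 166 cuticle collagen genes 91 fell and 19 rose, and 92 fell and 19 rose adjusted over the list alone, with a median log2 fold change of -1.77 (camera adjusted p = 1.36e-11; adjusted p = 0.245 with an estimated correlation). The lowest values, all with few reads left in high salt, were those of col-73 (F11G11.12), col-90 (C29E4.1), col-17, dpy-13 (F30B5.1) and rol-8 (ZK1290.3), at -11.06 ± 1.32, -10.99 ± 1.49, -10.87 ± 1.11, -9.61 ± 1.13 and -9.43 ± 1.28, and of sqt-1 (B0491.2), which fell from 548 ± 208 to 1.05 ± 0.916 CPM. The adult-stage collagen gene col-19 (ZK1193.1) stayed near the detection limit, at 0.257 ± 0.132 and 0.117 ± 0.121 CPM, with an adjusted p of 0.571. The 6 annular furrow collagen genes, which belong to the same family, all fell, over all genes and adjusted over the list alone, with a median of -5.30 (camera adjusted p = 4.75e-08; adjusted p = 0.215 with an estimated correlation). Among them were dpy-2 (T14B4.6) at -4.38 ± 0.44 and dpy-3 (EGAP7.1) at -5.42 ± 0.57. Of 74 molting genes 40 fell and 5 rose, and 42 fell and 7 rose adjusted over the list alone (camera adjusted p = 4.3e-07; adjusted p = 0.246 with an estimated correlation). They include mlt-10 at -3.70 ± 0.49, wrt-10 (ZK1290.8) at -6.08 ± 0.57 and grd-5 (F41E6.2) at -4.04 ± 0.32. Of 13 heterochronic genes 6 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.902). In that list lin-42 (F47F6.1), a period homolog that cycles with the molts, fell from 254 ± 85.4 to 5.06 ± 2.88 CPM, lin-29 (W03C9.4) fell by 3.74 ± 0.51 on the log2 scale, and lin-28 rose by 1.25 ± 0.31.

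Genes of protein synthesis, proteolysis, respiration and DNA replication fell in most members. Of 82 ribosomal protein genes 81 fell, 81 also adjusted over the list alone, with a median log2 fold change of -1.41 (camera adjusted p = 1.79e-19; adjusted p = 0.377 with an estimated correlation), and rpl-3 (F13B10.2) fell from 4224 ± 126 to 1399 ± 320 CPM. Of 33 proteasome genes 31 fell and 1 rose, and 32 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.95e-17; adjusted p = 0.245 with an estimated correlation). An example is pas-1 (C15H11.7) at -2.21 ± 0.25. Of 45 mitochondrial respiration genes 41 fell, and 43 adjusted over the list alone (camera adjusted p = 6.81e-15; adjusted p = 0.245 with an estimated correlation). Among them asb-1 stood at -2.44 ± 0.27. Of 46 cell cycle and DNA replication genes 34 fell and 1 rose, and 37 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.86e-13; adjusted p = 0.163 with an estimated correlation). These include the replication genes pcn-1 (W03D2.4) and mcm-4 (Y39G10AR.14) at -3.10 ± 0.31 and -2.73 ± 0.28 and the kinase gene cdk-1 (T05G5.3) at -2.41 ± 0.26. With upper-quartile scaling 78 ribosomal protein genes, 28 proteasome genes, 38 respiration genes and 29 cell cycle genes still fell. The rRNA share was 2.65% to 4.68% in the fed low-salt and 9.13% to 81.8% in the fed high-salt libraries.

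Many genes of digestion, fat oxidation and other lists fell too. Of 42 digestive enzyme genes 29 fell and 3 rose, in the same numbers adjusted over the list alone (camera adjusted p = 2.28e-10; adjusted p = 0.163 with an estimated correlation). Examples are the protease gene asp-13 (F28A12.4) at -3.90 ± 0.34 and the lysozyme gene lys-2 (Y22F5A.5) at -6.04 ± 0.54. Of 38 lipase and fatty-acid oxidation genes 27 fell and none rose, in the same numbers adjusted over the list alone, with a median of -2.40 (camera adjusted p = 7.59e-15; adjusted p = 0.0588 with an estimated correlation). The peroxisomal beta-oxidation genes maoc-1 (E04F6.3), dhs-28 (M03A8.1) and daf-22 (Y57A10C.6) fell, at -3.54 ± 0.28, -3.52 ± 0.29 and -3.12 ± 0.27 on the log2 scale, with ech-4 (R06F6.9) at -2.98 ± 0.23 and acs-2 at -3.25 ± 0.72. Of 19 vitamin B12, propionate and methionine genes 13 fell and 2 rose, in the same numbers adjusted over the list alone (camera adjusted p = 2.84e-06; adjusted p = 0.245 with an estimated correlation). Among them were acdh-1 down from 1353 ± 22.8 to 50.0 ± 17.6 CPM, metr-1 (R03D7.1) at -4.13 ± 0.46 and ech-6 (T05G5.6) at -4.38 ± 0.47. Of 12 glyoxylate, gluconeogenesis and glycogen genes 8 fell, 8 also adjusted over the list alone (camera adjusted p = 6.16e-05; adjusted p = 0.245 with an estimated correlation). Members of this list include icl-1, the glyoxylate cycle enzyme, at -2.62 ± 0.42. Of 22 fatty-acid synthesis genes 13 fell and 2 rose, and 14 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00137; adjusted p = 0.245 with an estimated correlation). Of 19 intestine markers 12 fell and 1 rose, and 13 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000506; adjusted p = 0.245 with an estimated correlation). Examples are act-5 (T25C8.2) at -3.44 ± 0.41 and pho-1 (EGAP2.3) at -3.69 ± 0.43. Of 18 endoplasmic reticulum stress genes 12 fell, 12 also adjusted over the list alone (camera adjusted p = 1.45e-07; adjusted p = 0.245 with an estimated correlation). Among them pdi-2 (C07A12.4) stood at -3.52 ± 0.35. Of 28 germline markers 18 fell and 1 rose, and 19 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000122; adjusted p = 0.245 with an estimated correlation). They include glh-1 at -2.75 ± 0.31 and pgl-1 at -2.86 ± 0.39.

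Osmolyte, antimicrobial, chaperone and insulin-signalling lists held members that rose and members that fell. Of 17 osmolyte and water transport genes 4 rose and 8 fell, and 5 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.541). The myo-inositol transporter genes hmit-1.2 (Y51A2D.5) and hmit-1.1 rose by 2.44 ± 0.29 and 0.86 ± 0.32 on the log2 scale, the latter at an adjusted p of 0.0454, while gpdh-2 fell by 1.97 ± 0.26. The aquaporin gene aqp-8 (K02G10.7) fell from 66.3 ± 5.01 to 13.6 ± 3.82 CPM. Of 21 epidermal antimicrobial peptide genes 7 rose and 4 fell, and 7 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.585). Examples are cnc-11 (R09B5.13) at 6.52 ± 0.95, cnc-7 (F53H2.2) at 4.57 ± 0.80, nlp-29 at 1.92 ± 0.55 and an adjusted p of 0.0127, and cnc-3 (R09B5.8) at -3.13 ± 0.42. Of 25 chaperone genes 4 rose and 5 fell, and 5 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.551). Among them were the small heat shock genes hsp-12.6 (F38E11.2) and hsp-12.3 (F38E11.1) up by 6.57 ± 0.88 and 2.35 ± 0.38 on the log2 scale. In the list of 17 genes raised by the FOXO factor DAF-16, 6 rose and 4 fell, and 8 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.551). The members sod-5, sod-3 and hsp-12.6 rose, sod-3 from 1.35 ± 0.138 to 51.9 ± 26.4 CPM, and icl-1, ctl-2 (Y54G11A.5) and lys-7 (C02A12.4) fell, the last by 5.03 ± 0.62 on the log2 scale. The transcript of daf-16 itself had a log2 fold change of 0.52 ± 0.26 and an adjusted p of 0.122, which was 0.00413 with upper-quartile scaling. Of 30 insulin-like peptide genes 3 rose and 7 fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.291). These include daf-28 down from 37.3 ± 17.4 to 3.13 ± 1.06 CPM, ins-35 (K02E2.4) at -4.15 ± 0.48 and ins-33 (W09C5.4) at -7.66 ± 0.99. Of 31 neuron markers 7 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0116, and 0.0518 without fed high-salt B; adjusted p = 0.679 with an estimated correlation). Of 30 muscle markers 7 rose and 6 fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.541). Examples are the pharyngeal myosin gene myo-2 (T18D3.4) up from 665 ± 251 to 3781 ± 773 CPM and myo-5 (F58G4.1) from 164 ± 50.0 to 2363 ± 377 CPM. Among all genes the highest log2 fold changes under the naming rule were those of D1086.9, C37A5.6, clx-1 (C50F7.2) and ttbk-5 (C04G2.2), at 11.14 ± 0.71, 9.69 ± 1.03, 9.04 ± 1.21 and 8.94 ± 0.79, all from under 0.4 CPM. F13A2.4, with 1 read in the 3 fed low-salt libraries together, stood at 20.2 ± 11.3 CPM in fed high-salt larvae.

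In this comparison 6898 of 18028 genes passed the test, 2905 higher and 3993 lower at 500 mM NaCl, and 5818 differed by more than 2-fold. With upper-quartile scaling the median log2 fold change of all genes went from 0.12 to 0.55, and 4750 genes rose and 2705 fell, so changes are given relative to the other genes, not per larva. In 62.5% of genes the groups did not overlap in CPM, where chance gives 10%, and 7642 genes passed without unfed high-salt A and fed high-salt C. Of the 63 called genes followed, 61 stayed called in all 12 fits with 1 library left out. The call of nlp-29 was lost without fed high-salt A or fed low-salt C, and that of hmit-1.1 in 10 of the 12 fits, without the count filter and with rRNA genes left out. The test missed most simulated 2-fold changes, so a gene that did not pass is not shown unchanged.

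**Figure D2:**
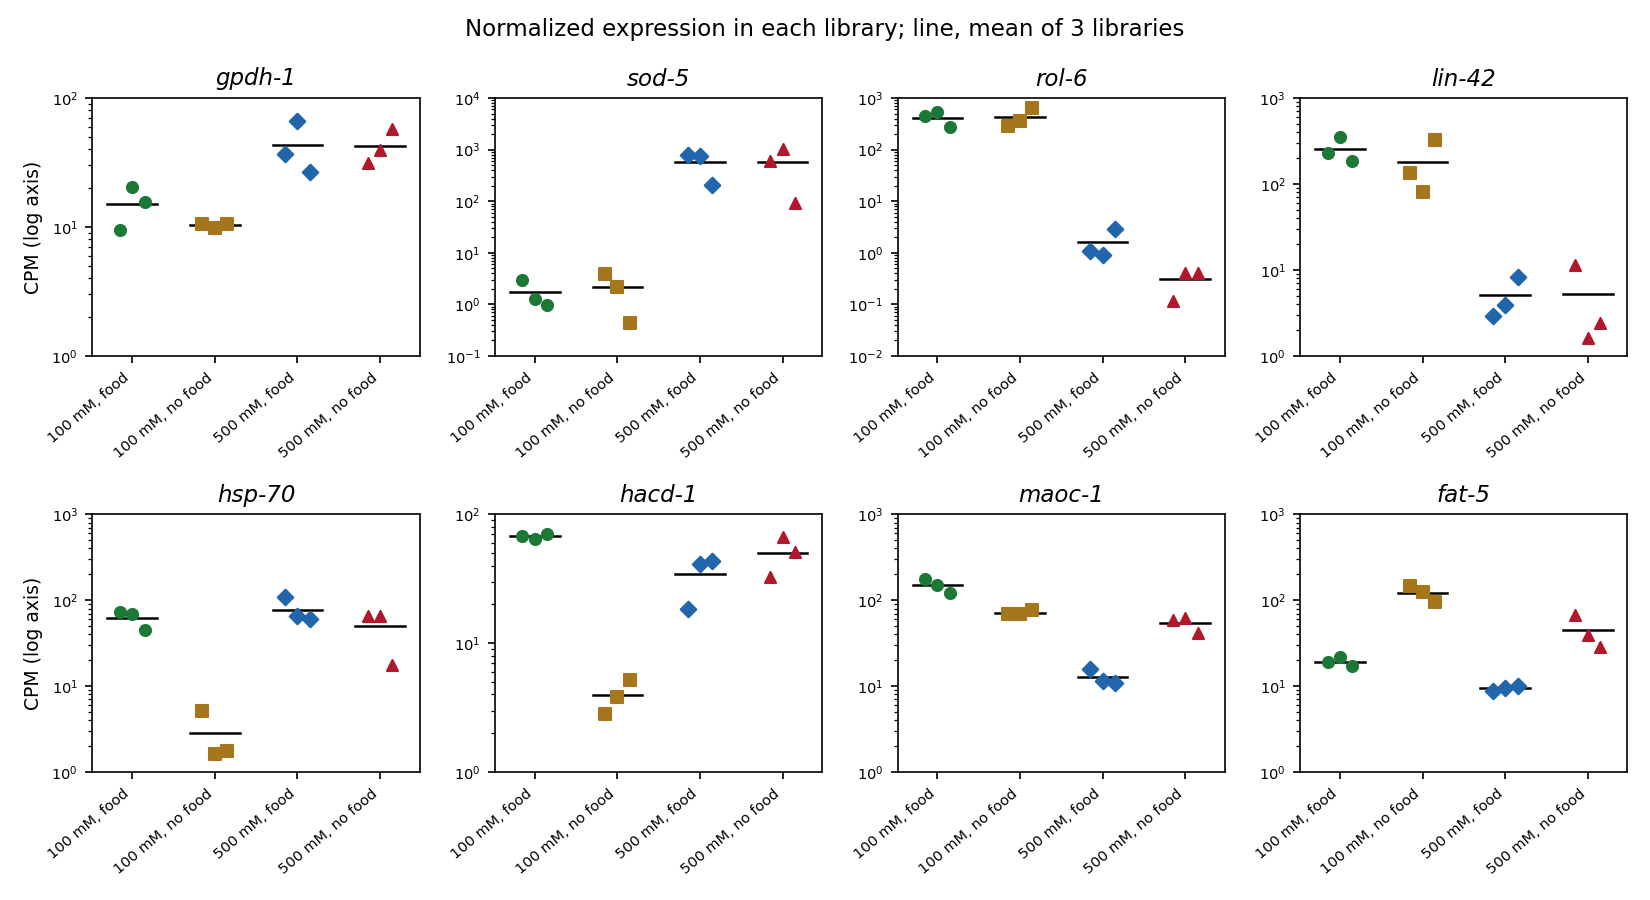
CPM (log axis) of 8 genes in each of the 12 libraries, 1 panel per gene and 1 point per library, with a line at the mean of 3 libraries of a group. In the panel of rol-6 the high-salt libraries lie far below the low-salt ones (means of 418 and 432 CPM against 1.61 and 0.311), in that of sod-5 far above, and in those of hsp-70 and hacd-1 the unfed low-salt libraries lie lowest (means of 2.84 and 3.95 CPM).

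High salt in the absence of food, unfed high-salt against unfed low-salt larvae, gave a similar set of changes. Collagen, molting, cell cycle and digestive genes fell in the counts given below, and 10 of 25 chaperone genes rose. The collagen gene rol-6 fell from 432 ± 186 to 0.311 ± 0.169 CPM, a log2 fold change of -10.27 ± 0.60 at an adjusted p of 1.05e-07, and gpdh-1 rose from 10.3 ± 0.448 to 42.8 ± 13.2 CPM, a log2 fold change of 2.06 ± 0.35 at an adjusted p of 0.000658. The transcript of hsp-70 rose from 2.84 ± 1.99 to 49.7 ± 27.6 CPM.

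Of 166 cuticle collagen genes 81 fell and 6 rose, and 87 fell and 8 rose adjusted over the list alone (camera adjusted p = 2.14e-15; adjusted p = 0.211 with an estimated correlation). Among them were col-17, col-41 (T10B10.1) and dpy-5 (F27C1.8) at -8.80 ± 0.99, -8.63 ± 0.68 and -8.34 ± 1.16. All 6 annular furrow collagen genes fell, 6 also adjusted over the list alone (camera adjusted p = 1.6e-12; adjusted p = 0.135 with an estimated correlation). Of these dpy-3 fell by 5.95 ± 0.59 on the log2 scale. Of 74 molting genes 34 fell and 6 rose, and 37 fell and 7 rose adjusted over the list alone (camera adjusted p = 3.36e-11; adjusted p = 0.258 with an estimated correlation). Members of this list include mlt-10 at -3.75 ± 0.49, and lin-42 of the heterochronic list stood at -5.20 ± 0.78. Of 19 epidermis markers 6 fell and 2 rose, and 6 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00384; adjusted p = 0.337 with an estimated correlation); their mean was -1.74, but their median of -0.17 became 0.12 with upper-quartile scaling. Of 46 cell cycle and DNA replication genes 30 fell, and 33 adjusted over the list alone (camera adjusted p = 4.09e-18; adjusted p = 0.135 with an estimated correlation). Examples are pcn-1, mcm-4 and cdk-1 at -2.51 ± 0.30, -2.34 ± 0.27 and -2.48 ± 0.26. Of 82 ribosomal protein genes 62 fell, and 79 adjusted over the list alone (camera adjusted p = 7.56e-16; adjusted p = 0.605 with an estimated correlation). Of 33 proteasome genes 17 fell and 1 rose, and 28 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.4e-07; adjusted p = 0.605 with an estimated correlation). Of 45 respiration genes 11 fell, and 24 adjusted over the list alone (camera adjusted p = 9.34e-06; adjusted p = 0.607 with an estimated correlation). The rRNA share was 1.32% to 12.4% in the unfed low-salt and 6.32% to 18.2% in the unfed high-salt libraries.

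Of 42 digestive enzyme genes 28 fell and 1 rose, in the same numbers adjusted over the list alone (camera adjusted p = 6.17e-13; adjusted p = 0.135 with an estimated correlation). Among them asp-13 stood at -3.49 ± 0.33. Of 38 lipase and fatty-acid oxidation genes 16 fell and 2 rose, and 18 fell and 2 rose adjusted over the list alone (camera adjusted p = 3e-06; adjusted p = 0.173 with an estimated correlation). In this list ech-4 stood at -2.38 ± 0.23. Chaperones rose: 10 of 25 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone, with a median of 0.99 (camera adjusted p = 4.8e-07; adjusted p = 0.431 with an estimated correlation). Examples are hsp-12.6, hsp-12.3 and F44E5.4 at 8.63 ± 0.98, 4.87 ± 0.44 and 3.59 ± 0.53. Of 30 insulin-like peptide genes 11 fell and none rose, and 12 fell adjusted over the list alone (camera adjusted p = 1.52e-05; adjusted p = 0.431 with an estimated correlation). Among them were daf-28 at -4.11 ± 0.37 and ins-35 at -4.53 ± 0.50. Of 18 endoplasmic reticulum stress genes 8 fell, 8 also adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.605 with an estimated correlation). The lists of gluconeogenesis (6 of 12 fell, 1 rose), vitamin B12 metabolism (9 of 19 fell, 3 rose) and intestine markers (10 of 19 fell, 2 rose) had camera adjusted p-values of 0.017, 0.0132 and 0.00521. These became 0.155, 0.208 and 0.107 without unfed high-salt A, and with an estimated correlation they were adjusted p = 0.607, adjusted p = 0.669 and adjusted p = 0.551. Adjusted over the list alone, 6 fell and 1 rose, 10 fell and 3 rose, and 11 fell and 2 rose. Of 28 germline markers 2 rose and 2 fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.548), fbf-2 (F21H12.5) rising by 2.75 ± 0.26 on the log2 scale. Of 17 osmolyte and water transport genes 4 rose and 3 fell, and 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.6). These include hmit-1.2 at 3.27 ± 0.30, hmit-1.1 at 0.75 ± 0.32 and an adjusted p of 0.123, and gpdh-2 at -0.98 ± 0.25. Of the 17 DAF-16 genes 4 rose and 5 fell, and 5 rose and 5 fell adjusted over the list alone, with sod-3 at 4.41 ± 0.59 and lys-7 at -6.29 ± 0.65. Both hacd-1 and elo-2, which fell without food at low salt, rose, by 3.66 ± 0.37 and 2.12 ± 0.35 on the log2 scale, and daf-7 fell by 2.02 ± 0.26. The highest log2 fold changes under the naming rule were those of D1086.9, clx-1, hsp-12.6, C37A5.5, sod-5 and C37A5.6, from 10.26 ± 0.68 down to 7.89 ± 0.91.

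Here 3230 genes passed the test, 1212 higher and 2018 lower at 500 mM NaCl, and 2757 differed by more than 2-fold. With upper-quartile scaling 1783 rose and 1750 fell, and the median log2 fold change of all genes went from 0.08 to 0.24. In 29.1% of genes the groups did not overlap, where chance gives 10%, and 4619 genes passed without unfed high-salt A and fed high-salt C. Of the 38 called genes followed, 36 stayed called in every fit with 1 library left out, and the calls of gpdh-2 and nlp-29 were lost without unfed high-salt B or without unfed low-salt C. Across all 18028 genes the salt effects with and without food, which share no library, had a correlation of 0.698, and of the 2515 genes called in both, 2494 moved the same way and 21 opposite ways, against 642 and 594 for independent lists of these sizes. That correlation is across genes, which are not independent replicates.

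**Figure D3:**
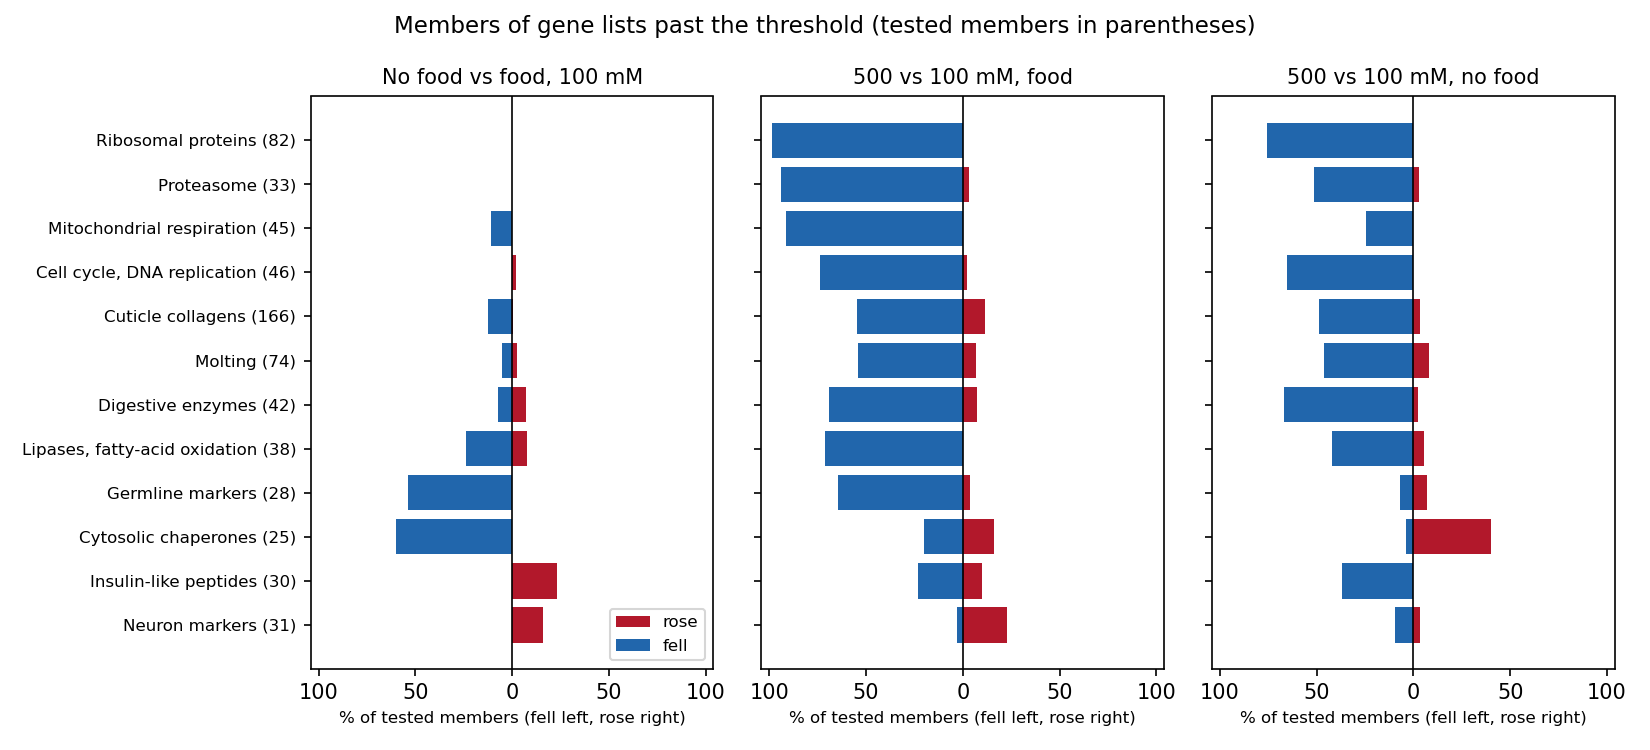
Percentage of the tested members of 12 gene lists that passed the test, with members that fell drawn to the left of 0 and members that rose to the right, for no food against food at 100 mM NaCl, for 500 against 100 mM NaCl with food, and for 500 against 100 mM NaCl without food. Ribosomal protein genes fell at 500 mM NaCl (81 of 82 with food, 62 of 82 without) and none passed the test for lack of food, and chaperones fell without food at 100 mM NaCl (15 of 25).

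The responses to lack of food and to high salt were then compared as changes from the same fed low-salt larvae. Both comparisons had lower transcripts of the germ granule genes glh-1 and pgl-1, of acs-2, acdh-1 and asb-1, and higher transcripts of lin-28. Of 82 ribosomal protein genes 81 fell in high salt and none passed the test for lack of food, a difference that the direct comparison of both arrests tests. Of 992 genes called in both comparisons 942 moved the same way, 363 up and 579 down, and 50 moved opposite ways. Independent lists of these sizes would give 268 and 262. In 20 simulations of unchanged groups against the same controls at most 2 genes were called, so their overlap (at most 1) decides nothing. The correlation across genes was 0.671, with a jackknife SE over libraries of 0.199, against 0.485 on average (0.465 to 0.504) in the simulations. Over genes above 10 CPM it was 0.521, inside the simulated range of 0.478 to 0.528. The simulated groups hold no change, and real changes can alter the correlation that shared controls give. The correlation thus does not tell shared changes from shared controls. Over all genes the covariance was 1.43 against 0.149, a difference of 1.28, and it was not taken above 10 CPM alone. With 3 control libraries no split into parts of at least 2 is possible, so part of the excess may come from the shared controls. The count of 942 was 244, 149 and 203 without fed low-salt A, B and C, 197, 155 and 1549 without unfed low-salt A, B and C, 604 and 543 without fed high-salt A and B, and 2066 without unfed high-salt A.

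Set directly against unfed low-salt larvae, fed high-salt larvae had lower transcripts of many collagen, ribosomal protein, cell cycle and digestive genes. Some insulin-like peptide genes were lower and some chaperone genes higher. The genes D1086.9, clx-1 and sod-5 were higher in osmotic than in starvation arrest by 10.17 ± 0.68, 9.99 ± 1.32 and 8.06 ± 1.06 on the log2 scale, and gpdh-1 was higher by 2.08 ± 0.35 at an adjusted p of 0.00058. The collagen genes col-17 and col-90 stood at -10.76 ± 1.11 and -10.08 ± 1.46, and daf-28 at -3.86 ± 0.37. Lower in fed high-salt larvae were 80 of 82 ribosomal protein genes (camera adjusted p = 2.95e-27; adjusted p = 0.393 with an estimated correlation) and 80 of 166 collagen genes, with 10 higher (camera adjusted p = 1.66e-12; adjusted p = 0.313 with an estimated correlation). So were 32 of 46 cell cycle genes (camera adjusted p = 8.93e-16; adjusted p = 0.125 with an estimated correlation) and 28 of 42 digestive enzyme genes with 1 higher (camera adjusted p = 1.48e-14; adjusted p = 0.107 with an estimated correlation). Adjusted over the list alone, 81 ribosomal, 83 collagen, 36 cell cycle and 29 digestive genes were lower, and 14 collagen genes and 1 digestive gene higher. Of 38 fatty-acid oxidation genes 24 were lower and 1 higher, 25 and 1 adjusted over the list alone (camera adjusted p = 2.01e-13; adjusted p = 0.0904 with an estimated correlation). Of 30 insulin-like peptide genes 11 were lower, 11 also adjusted over the list alone (camera adjusted p = 2.13e-05; adjusted p = 0.393 with an estimated correlation). Of 25 chaperone genes 9 were higher and 1 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 1.2e-07; adjusted p = 0.393 with an estimated correlation). In the list of muscle markers 7 of 30 were higher and 1 lower, in the same numbers adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.723 with an estimated correlation), and 1 of 28 germline markers was higher and 1 lower. In total 3885 genes passed the test, 1269 higher and 2616 lower, and 3266 differed by more than 2-fold. With upper-quartile scaling 2226 were higher and 2049 lower, and the median log2 fold change of all genes went from -0.08 to 0.12. The count was 2497 without fed high-salt B and 4451 without unfed high-salt A and fed high-salt C. Of 20 called genes followed, 19 stayed called in all 12 fits with 1 library left out, and nlp-29 was lost without fed high-salt A.

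Lack of food at 500 mM NaCl, unfed against fed high-salt larvae, changed few genes by the test. Some peroxisomal beta-oxidation genes were higher without food: maoc-1 rose by 2.08 ± 0.27 on the log2 scale at an adjusted p of 0.00668. In the same comparison daf-22 rose from 34.8 ± 5.72 to 115 ± 15.0 CPM and acox-1 (F08A8.1) from 21.9 ± 2.16 to 64.5 ± 1.21 CPM. The desaturase gene fat-5 rose from 9.52 ± 0.703 to 45.3 ± 20.1 CPM, and the only gene that fell was abu-14 (ZK1067.7), from 94.0 ± 13.9 to 14.1 ± 1.01 CPM. The other genes of the naming rule that rose were irg-3 (F53E10.4), acs-7 (C01G6.7) and acds-10 (K09H11.1), by 2.67 ± 0.46, 2.19 ± 0.38 and 1.73 ± 0.25 on the log2 scale. The remaining calls, named after their values were seen, were B0272.4, mecr-2 (Y48A6B.9), dhrs-4 (F54F3.4), ceeh-2 (K07C5.5), pmp-2 (C44B7.9) and nhr-11 (ZC410.1). The first 5 rose by 2.44 ± 0.30, 1.78 ± 0.30, 1.69 ± 0.27, 1.68 ± 0.29 and 1.42 ± 0.24, and nhr-11 went from 7.84 ± 2.32 to 22.2 ± 1.44 CPM. Of 38 lipase and fatty-acid oxidation genes 3 rose and none fell, and 13 rose adjusted over the list alone, with a median log2 fold change of 0.75 (camera adjusted p = 4.62e-10; adjusted p = 0.142 with an estimated correlation). The member dhs-28 had a log2 fold change of 1.23 ± 0.27 and an adjusted p of 0.128, and ugt-66 (C23G10.6), a glucuronosyltransferase gene, 1.88 ± 0.34 and an adjusted p of 0.0588. Ribosomal protein genes had a median of 0.36, and none passed the test (camera adjusted p = 5.4e-10, and 0.262 without fed high-salt C, the library with 81.8% rRNA; adjusted p = 0.905 with an estimated correlation). Of the focal genes neither gpdh-1, gpdh-2, hmit-1.1, nlp-29, sod-3, daf-16, daf-28, icl-1, acdh-1, acs-2 nor mlt-10 passed the test, with adjusted p-values of 0.431 (icl-1) to 0.997 (nlp-29).

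In all 14 genes passed the test, 13 higher and 1 lower without food, each by more than 2-fold, and 1428 had an unadjusted p under 0.05. Upper-quartile scaling gave 10 higher and 3 lower, leaving out the rRNA genes 15 higher and 4 lower, DESeq2 98 genes and edgeR's exact test 78. In 10.2% of genes the groups did not overlap in CPM, which is the share chance gives (10%). The count was 6 and 7 without fed low-salt A and B, 7 without unfed low-salt A, 2 without fed high-salt A, 32 and 9 without unfed high-salt B and C, and 9 without unfed high-salt A and fed high-salt C. Without fed high-salt B or without fed high-salt C edgeR's quasi-likelihood test called 0 genes, while 1049 and 1243 genes then had an unadjusted p under 0.05. Each of the 14 calls was lost in at least 1 of the 12 fits, B0272.4 and maoc-1 only without fed high-salt B or C. Of the 13 lists called in this comparison 1, fatty-acid oxidation, stayed called in all 12 fits.

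Whether lack of food acted differently in high and low salt was tested with the interaction, the effect of no food at 500 mM NaCl minus that at 100 mM NaCl. Positive values passed the test in 10 of 38 fatty-acid oxidation genes, 6 of 25 chaperone genes and 6 of 28 germline markers, and in the elongase genes elo-2, elo-5 and elo-6. The gene hacd-1 had means of 67.5, 3.95, 34.3 and 49.9 CPM in fed low-salt, unfed low-salt, fed high-salt and unfed high-salt larvae, an interaction of 4.65 ± 0.49 on the log2 scale at an adjusted p of 0.000583. The corresponding means of maoc-1 were 150, 71.7, 12.8 and 54.4 CPM, an interaction of 3.14 ± 0.37 at an adjusted p of 0.00136. The thaumatin genes thn-1 (F28D1.3) and thn-2 (F28D1.5), which rose without food at 100 mM NaCl, had negative values of -3.72 ± 0.50 and -3.99 ± 0.56.

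Of 38 lipase and fatty-acid oxidation genes 10 had a positive and none a negative interaction, 16 and 1 adjusted over the list alone, with a median of 1.22 (camera adjusted p = 7.52e-11; adjusted p = 0.0493 with an estimated correlation). Examples are acox-2 at 5.30 ± 0.63 and daf-22 at 2.68 ± 0.35. The other list whose call held with an estimated correlation was that of 67 glucuronosyltransferase genes, 7 positive and 1 negative, 13 and 1 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 2.08e-05; adjusted p = 0.0493 with an estimated correlation). Among them were ugt-62 (M88.1) and ugt-64 (C07G3.9) at 2.99 ± 0.52 and 1.70 ± 0.31. Of 25 chaperone genes 6 were positive, and 13 adjusted over the list alone, with a median of 1.52 (camera adjusted p = 1.75e-11; adjusted p = 0.333 with an estimated correlation). Members of this list include F44E5.4 at 4.62 ± 0.71 and hsp-70 at 3.80 ± 0.70. Of 28 germline markers 6 were positive, 2 with upper-quartile factors and 15 adjusted over the list alone, with a median of 1.51. The camera adjusted p was 1.11e-10, and 0.0996 with an estimated correlation. Examples are glh-1 at 1.89 ± 0.41 and fbf-2 at 1.70 ± 0.35. Of 22 fatty-acid synthesis genes 4 were positive, and 6 adjusted over the list alone (camera adjusted p = 0.000446; adjusted p = 0.507 with an estimated correlation). Among them were elo-5, elo-2 and elo-6 at 3.81 ± 0.56, 2.89 ± 0.48 and 2.46 ± 0.38. The highest values under the naming rule were those of lep-5, irg-8 (ZK6.11), acox-2 and K08D8.4, at 6.21 ± 1.15, 5.97 ± 0.89, 5.30 ± 0.63 and 4.71 ± 0.68. The lowest were those of T26H5.9 and scl-2 (F49E11.10), at -4.39 ± 0.95 and -4.11 ± 0.83. F13A2.4, whose fitted value was -4.93 ± 1.12, had 1 read in the fed low-salt libraries, so that this value depends on the prior count. The focal genes gpdh-1, gpdh-2, sod-3, daf-28, acs-2 and acdh-1 did not pass, with adjusted p-values of 0.594, 0.151, 0.607, 0.551, 0.402 and 0.812.

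In all 360 genes had an interaction past the test, 282 positive and 78 negative, each by more than 2-fold, and 3233 had an unadjusted p under 0.05. Upper-quartile scaling gave 185 positive and 194 negative values and moved the median of all genes from -0.04 to -0.30. The count was 102, 63 and 94 without fed low-salt A, B and C, 65, 87 and 924 without unfed low-salt A, B and C, 151, 76 and 178 without fed high-salt A, B and C, 967 without unfed high-salt A, and 630 without unfed high-salt A and fed high-salt C. Of 27 called genes followed 16 stayed called in all 12 fits with 1 library left out: F44E5.4, F44E5.5, K08D8.4, acox-2, daf-22, elo-2, elo-5, elo-6, hacd-1, irg-8, lys-2, maoc-1, pgp-1 (K08E7.9), thn-1, thn-2 and ugt-62. The calls of F13A2.4, T26H5.9, col-165 (F14H12.1), fbf-2, glh-1, hsp-12.3, hsp-70, lep-5, scl-2, daf-9 and ugt-64 were lost in at least 1.

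Against the authors' deposited tables of edgeR's exact test, matched by gene, the calls here were a subset with few exceptions. Of 1382 matched genes called here for lack of food at 100 mM NaCl, 1381 were among the 2217 called there, and of 14 at 500 mM NaCl all 14 were among 85. For high salt 6540 of 6696 calls with food were among 7244, and 3172 of 3187 without food among 3716. The correlations of log2 fold changes across genes were 0.999 or higher, and every shared call had the same sign.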

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

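The counts of other splits of the samples, the test on scaling and the tests on unfed high-salt A and unfed low-salt C were chosen after the results were seen, except the test on genes that rose in unfed low-salt A and B, which was set down before, as was the test on fatty-acid oxidation genes without 2 libraries.

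Lack of food acted differently at 500 than at 100 mM NaCl in 360 genes by the interaction. Among lists, positive median interactions stood at 1.52 for chaperones, 1.51 for germline markers, 1.22 for fatty-acid oxidation, 0.86 for the nucleolus, 0.83 for the proteasome, 0.75 for glucuronosyltransferases, 0.72 each for gluconeogenesis, respiration and vitamin B12 metabolism, 0.68 for glycolysis, 0.54 for endoplasmic reticulum stress, 0.45 for fatty-acid synthesis and 0.41 for ribosomal proteins. Negative medians stood at -0.92 for insulin-like peptides and -0.32 for neuron markers. With an estimated correlation adjusted p-values in the same order were 0.333, 0.0996, 0.0493, 0.609, 0.575, 0.0493, 0.609, 0.575, 0.575, 0.627, 0.627, 0.507 and 0.870 for the positive lists, and 0.627 and 0.767 for the negative ones. The list calls of insulin-like peptides (without unfed low-salt B or fed high-salt A), ribosomal proteins (without fed high-salt C) and neuron markers (without unfed high-salt A) were lost, at adjusted p-values of 0.0994, 0.083, 0.0535 and 0.379.

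Positive log2 interactions by gene were 6.21 (lep-5), 5.97 (irg-8), 5.30 (acox-2), 4.71 (K08D8.4), 4.65 (hacd-1), 4.63 (F44E5.5), 4.62 (F44E5.4), 3.84 (lys-2), 3.81 (elo-5), 3.80 (hsp-70), 3.14 (maoc-1), 2.99 (ugt-62), 2.89 (elo-2), 2.83 (pgp-1), 2.72 (daf-9), 2.68 (daf-22), 2.52 (hsp-12.3), 2.46 (elo-6), 1.89 (glh-1), 1.70 (ugt-64) and 1.70 (fbf-2). Negative ones were -4.93 (F13A2.4), -4.39 (T26H5.9), -4.11 (scl-2), -3.99 (thn-2), -3.85 (col-165) and -3.72 (thn-1).

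Shares of reads outside the gene analysis were above the highest fed low-salt library in many others. Reads on rRNA genes, 4.68% at most in fed low-salt libraries, were 6.61% and 12.4% in unfed low-salt A and C, 9.13%, 39.9% and 81.8% in fed high-salt A, B and C, and 14.9%, 6.32% and 18.2% in unfed high-salt A, B and C. Reads on no feature, also above each fed low-salt library, were 5.90%, 5.85% and 2.56% in unfed low-salt A, B and C, 5.41%, 3.61% and 2.22% in fed high-salt A, B and C, and 17.1%, 4.77% and 4.02% in unfed high-salt A, B and C. Ambiguous reads, 4.01% at most there, were 4.26% in unfed low-salt C, 4.35%, 6.84% and 10.99% in fed high-salt A, B and C, and 4.56%, 4.21% and 5.17% in unfed high-salt A, B and C. Reads not aligned were 22.4% and 20.5% in unfed low-salt A and B, 29.9% and 22.4% in fed high-salt A and B, and 61.4% in unfed high-salt A.

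Unfed high-salt A stands apart from the other high-salt libraries, and among 4481 genes under 1 CPM in unfed high-salt B and C its median log2 excess over these was 1.75, against -0.67 in 1464 genes over 100 CPM. A low-salt library under a wrong label is argued against: between fed low-salt (0) and fed high-salt (1) the median position of A over 616 genes was 0.81, with quartiles of 0.655 and 0.983. Reads spread over the genome, from genomic DNA or unspliced RNA, are a candidate explanation: across the nearly silent genes the excess rose with the span of the gene (Spearman rho = 0.343), from a median of 1.08 in the shortest 20% of genes to 2.33 in the longest 20%. Of non-rRNA gene reads, 1686 genes with chemoreceptor-type symbols held 1.12% in A and 0.330 to 0.570% in the other 11 libraries. No biological explanation was tested.

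Unfed low-salt C correlated with fed low-salt libraries at 0.960 to 0.967 and with unfed low-salt A and B at 0.944 to 0.945. A swap with a fed library is argued against, since the lowest correlation among fed libraries exceeded the highest of any of them with A or B by 0.0521. Mixing with fed material in a single proportion is argued against for 118 genes that rose without food. They would need a median share of fed RNA 0.469 above that of genes that fell (quartiles 0.592 and 0.841 against 0.130 and 0.455). Both sets were picked in A and B, with background reads not accounted for. For 261 genes that fell the median share was 0.289, with 55 under 0.1 and 51 over 0.5. Shares ran from -0.183 (irg-1, lower in C than in A and B) to 1.825 (pitr-5). Quartiles 0.325 apart, between under 0.2 expected from mixing and over 0.4 without it, cannot tell mixing from a library that changed less. A weaker response of that culture stays open and was not tested.

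Of 38 fatty-acid oxidation genes 9 fell and 3 rose without food at 100 mM NaCl (adjusted p = 0.226 with an estimated correlation), and 3 rose and none fell at 500 mM NaCl. Without unfed high-salt A and fed high-salt C the median interaction of the list was 1.103, which argues against these libraries as the whole cause. With upper-quartile factors, which moved the median of all genes from -0.04 to -0.30, it was 1.016, the lowest of 3 scalings. That shift is too small to remove a median of 1.22, and relative to all genes the median cannot move with a common factor. Neither test decides on scaling. A dependence of the response on salt stays a hypothesis, since scaling or a structure of the high-salt libraries other than food is not excluded.

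The interaction count of 360 was reached by 3 of 100 splits, the real one included. The other such splits, with 629 and 1124 genes, kept the low-salt groups whole, and splits that did not gave 0 or 1 gene. The share of 3 in 100 thus rests on the low-salt grouping and does not exclude chance. Of the 20 splits that keep the low-salt groups whole, 4 gave 360 or more. Chance is thus not excluded for a grouping of the high-salt libraries. Splits with 1124 and 629 genes group fed high-salt A and B with unfed B, leaving fed C (81.8% rRNA) with unfed A (38.6% aligned). The one with 874 also keeps fed C with unfed A, but other such splits gave 73 to 297. A structure other than food stays open. For lack of food at 500 mM NaCl, 2 of 10 splits gave 14 or more genes, the other 140 by the grouping with 1124 genes. For the other comparisons 1 of 10 splits each gave as many genes, the real one. Their real counts were 1384 for lack of food at 100 mM NaCl, 6898 and 3230 for high salt with and without food, and 3885 for fed high-salt against unfed low-salt larvae. By edgeR's quasi-likelihood test the highest other split gave 0 genes in each of these 4, with at most 1685, 361, 3512 and 921 genes at an unadjusted p under 0.05, and no other tool was run on the splits. With 10 splits a share under 0.05 is out of reach.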

How the results depend on the processing

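Alternatives chosen after the data were seen are those named above. No named gene with a call changed its direction in a setting run on named genes. Medians of called lists did: with upper-quartile factors collagens for lack of food at 100 mM NaCl went from -0.06 to 0.11, and C-type lectins and epidermis markers for high salt without food from -0.15 to 0.10 and from -0.17 to 0.12. Without rRNA genes these lectins stood at 0.03, and without unfed high-salt A and fed high-salt C 2 lists for lack of food at 500 mM NaCl, autophagy and muscle, turned positive and lost their calls. RLE and upper-quartile factors, leaving out rRNA genes and a fit without robust estimation moved no total count of genes by more than 1.5 times. By direction upper-quartile factors took genes that rose from 643 to 1099 for lack of food at 100 mM NaCl, from 2905 to 4750 for high salt with food and from 1269 to 2226 for fed high-salt against unfed low-salt larvae. They took positive interactions from 282 to 185 and negative ones from 78 to 194, and genes that fell for lack of food at 500 mM NaCl from 1 to 3, and leaving out rRNA genes took these to 4. DESeq2 gave 2690 genes for lack of food at 100 mM NaCl, 98 for lack of food at 500 mM NaCl, 1301 for the interaction and 1862 for the overlap of both arrests, and a correlation of 0.469 between them. edgeR's exact test gave 2134, 78 and 1462 for both effects of food and the overlap. With no count filter the effect of food at 500 mM NaCl had 207 genes, the interaction 1019 and the correlation was 0.460, and with a filter of 5 CPM in 3 libraries the interaction had 606. Fits of only the 2 groups compared gave 3524 and 1 for lack of food at 100 and 500 mM NaCl, 1811 for high salt without food and 2329 for the overlap. With the no-feature share as a covariate the interaction had 1130 genes and the overlap 1478. Without unfed high-salt A and fed high-salt C there were 3238 for lack of food at 100 mM NaCl, 9 at 500 mM NaCl, 630 for the interaction and 2116 for the overlap. Voom gave 5885 and 24 for lack of food at 100 and 500 mM NaCl, 10441 for high salt with food, 1652 for the interaction and 4011 for the overlap, with weights from 0.262 (unfed high-salt A) to 3.20 (fed low-salt B). For all of these the cause was not tested. With an estimated correlation 2 of 102 list calls held, because that setting widens the null spread of each list. The interaction was not run by the exact test or in fits of 2 groups, which compare pairs only.

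Fits without 1 library gave 218 to 2989 genes for lack of food at 100 mM NaCl, 4823 to 8703 and 2212 to 4209 for high salt with and without food, 0 to 32 for lack of food at 500 mM NaCl, 63 to 967 for the interaction and 2497 to 5201 for fed high-salt against unfed low-salt larvae. The 0 stands without fed high-salt B or C by edgeR's quasi-likelihood test, with 1049 and 1243 genes at an unadjusted p under 0.05. The overlap ranged from 149 to 2066, the correlation from 0.474 to 0.722 and list calls from 101 to 121. Fewer libraries lower the degrees of freedom, but the cause of the higher counts was not tested.

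With the replicate letter as a block there were 1673 and 30 genes for lack of food at 100 and 500 mM NaCl, 7351 and 3410 for high salt with and without food, 585 for the interaction and 4098 for fed high-salt against unfed low-salt larvae. The overlap with that block was 1188, the correlation 0.647 and the list calls 105. The values at 500 mM NaCl and for the interaction moved by more than 1.5 times, and the cause was not tested. Of 18 pairs of libraries that share a letter 7 correlated above 0.1 after group means were removed, with a range of -0.094 to 0.352, and 8 of 12 libraries correlated best with a library of their own letter. The rule that every such pair should exceed 0.1 was not met, which does not exclude a pairing by letter. The 8 of 12 is a hint of such a pairing from the data, not from the design.

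Of 245 named results by gene RLE changed no call. DESeq2, which gave 244, added 7 calls, no count filter added 3 and lost 3, leaving out rRNA genes lost 2, the block added 1 and lost 3, upper-quartile factors added 4 and lost 5, and leaving out both libraries added 4 and lost 7. Fits without 1 library lost 3 (unfed high-salt A) to 36 (fed low-salt B). Depth and sample number limit small changes. On simulated counts with few changed genes edgeR recovered 4 of 100 changed by 2-fold and 61 by 4-fold, with 13 false calls. DESeq2 recovered 17 and 71, with 58.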

Other observations

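Among genes of detoxification, glucuronosyltransferases fell with high salt in fed larvae. Of 67 glucuronosyltransferase genes, whose products attach sugars to small molecules, 31 fell and 6 rose in fed high-salt against fed low-salt larvae, with the same numbers adjusted over the list alone and a median log2 fold change of -0.90 (camera adjusted p = 0.000122; adjusted p = 0.0736 with an estimated correlation). Without food at 100 mM NaCl 9 fell and 3 rose, 14 and 5 adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.00292; adjusted p = 0.181 with an estimated correlation). The member ugt-16 (ZC443.6) fell from 47.2 ± 3.40 to 13.2 ± 2.49 CPM, a log2 fold change of -1.84 ± 0.27. Of 80 cytochrome P450 genes 23 fell and 12 rose with high salt in fed larvae (13 rose adjusted over the list alone; camera adjusted p = 0.541), while upper-quartile scaling turned this to 18 risen and 11 fallen. In unfed larvae 11 fell and 5 rose with high salt, 13 and 6 adjusted over the list alone (camera adjusted p = 0.0411; adjusted p = 0.78 with an estimated correlation). That list call was lost without unfed low-salt A, unfed low-salt B or unfed high-salt C (adjusted p = 0.160, 0.0562 and 0.256). Of 49 glutathione S-transferase genes 17 fell and 5 rose with high salt in fed larvae (6 rose adjusted over the list alone; camera adjusted p = 0.0525). In unfed larvae 12 fell and 6 rose, 15 and 7 adjusted over the list alone (camera adjusted p = 0.123). Of 183 C-type lectin genes 52 fell and 15 rose in fed high-salt larvae, the same numbers adjusted over the list alone (camera adjusted p = 0.132). The member clec-47 (T09F5.9), stood at 71.5 ± 6.06 CPM in fed low salt and 0.207 ± 0.155 CPM, 8 reads in all, in fed high salt. Without food 31 fell and 5 rose with high salt, again the same numbers adjusted over the list alone (camera adjusted p = 0.00584; adjusted p = 0.78 with an estimated correlation). That call was lost without unfed high-salt B (0.477) or C (0.157). With upper-quartile scaling the median of the lectins went from -0.04 to 0.46 in fed and from -0.15 to 0.10 in unfed larvae, so no direction of the list as a whole is given.

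Among lists of growth and tissue, 2 of 26 nucleolus genes fell without food at 100 mM NaCl, and 8 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 1.86e-05; adjusted p = 0.444 with an estimated correlation). With high salt 8 of these fell in fed larvae, but 1 fell and 2 rose with upper-quartile factors. Adjusted over the list alone 6 fell (camera adjusted p = 0.207). In unfed larvae 1 rose, also adjusted over the list alone. The camera adjusted p was 0.0314, and 0.78 with an estimated correlation. That call was lost without unfed low-salt A (0.137) or B (0.105) or unfed high-salt B (0.0707) or C (0.524). Of the muscle markers 2 fell without food at 100 mM NaCl, among them the troponin T gene tnt-2 (F53A9.10), from 576 ± 116 to 204 ± 81.7 CPM (camera adjusted p = 0.0104; adjusted p = 0.835 with an estimated correlation). The call of this list was lost without fed low-salt C (0.0647) or unfed low-salt B (0.0506). Of the intestine markers 3 fell and 1 rose, 4 and 1 adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.453 with an estimated correlation). The transporter gene pgp-1 of this list stood at -2.04 ± 0.35. Of 28 ion transport genes 2 fell without food at 100 mM NaCl. With high salt in fed larvae 6 rose and 4 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.674). Of 25 insulin, TOR and AMPK pathway genes 3 rose and 3 fell there, 2 and 2 adjusted over the list alone (camera adjusted p = 0.498). Upper-quartile factors turned 6 and 4 into 11 and 2, and 3 and 3 into 9 and 0. The 4 vitellogenin (adult yolk) genes tested had adjusted p-values of 0.0757 (vit-6, high salt in fed larvae) or more in every comparison. The CPM of vit-2 was 0.490 ± 0.226 in fed low-salt and 3.78 ± 5.01 in unfed high-salt larvae.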
